A study of Homo sapiens with 29 samples.

How the data were processed

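The data comprised 4 bulk RNA libraries, 2 of HUES8 ESC and 2 of converted EPSC, and 25 single feeder-free EPSC. Samples were grouped by their titles and cell types in the labels. Per the labels' protocols, total RNA of both bulk groups was prepared in duplicate and made into libraries with a directional kit, and the single cells were prepared by Smart-seq2. The labels do not say that the duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

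The authors deposited the bulk data as TPM, a unit normalized for gene length and library size, in which each library sums to the same total and the read depth is lost. Per the submitters' processing notes, the tools for the bulk libraries were cutadapt, HISAT2 2.1.0, featureCounts and DESeq2 on hg38. The single cells were deposited by the authors as raw read counts per gene, and their notes name HISAT2 and featureCounts with hg38 and GRCh38. The annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Both tables list the same 19907 gene symbols, of which 18796 matched the current symbols of gencode 44 and 479 an older symbol, while 632 were not matched, among them 12 dates, as a spreadsheet writes some gene names. Coordinates are those of gencode 44 on hg38, the build that the notes name. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and near-identical paralogs are uncertain.

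Bulk values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation with an intensity trend) over 13122 genes with a mean of at least 1 TPM in the 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and no fold is given where a group is listed at 0. The 49 gene lists cover pluripotency states, lineages, other cell types, metabolism, chromatin, signalling, stress and growth. Of them 48 had at least 5 measured members and were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01. Of the lists' memberships 1249 were found in the tables and 8 were not. The tests were run on simulated data with the means and spread of the comparison of EPSC with HUES8 ESC over 13122 genes. Of 200 simulated changed genes, those changed by 1 on the log2 scale were recovered in 98% of cases and those changed by 2 in 100%, while 17 unchanged genes were called (6.09% of calls). All 5 simulated lists were recovered with the preset correlation and 0 of 5 with an estimated correlation, and 0 other lists were called. The changed genes were drawn only from those expressed in HUES8 ESC well above the filter, and the shifted lists only from the larger lists. Recovery of genes near the filter and of small lists was therefore not measured. Genes were simulated independently of one another, so the simulation does not show how often lists of correlated genes would be called by mistake.

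The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names the 8 genes with the largest change in each direction among those past the threshold with both EPSC libraries on the same side of both HUES8 ESC libraries, a mean of at least 10 TPM in the higher group and a gene symbol. It also names up to 3 members per list with the smallest p, or the most abundant member where none passed, and POU5F1, SOX2 and NANOG. Some genes that this rule takes are not reported here. For the single cells it names these 3 genes, up to 3 members per list detected in the most cells, and the 8 genes with the largest residual of the squared coefficient of variation on the mean, by lowess with a fraction of 0.3 over genes with a mean of at least 50 CPM.

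A gene was called detected in a cell with at least 1 read, no cell was left out, and CPM were computed from the deposited counts. Smart-seq2 reads carry no molecular identifiers, and exact Clopper-Pearson 95% intervals cover counting error only. A count of 0 cells allows up to 12% by a limit of 3 of 25 cells, or 13.7% by the exact interval. Each cell was compared with the mean TPM of each bulk group by Spearman's rho across genes. Cells simulated from the EPSC profile were closer to EPSC in 25 of 25 cases, and cells simulated from the HUES8 ESC profile in 0 of 25. These were drawn from the bulk profiles they were compared with, without the differences between the assays. They show only that the measure can tell these 2 profiles apart. This used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.

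Parts of the reference that alternate contigs of hg38 also cover were found by aligning 261 alternate contigs to the primary chromosomes with minimap2 2.31, keeping alignments of at least 10000 bases with a divergence of at most 0.05. These gave 195 regions over 59.35 megabases, with 666 genes of the tables inside.

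The alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 TPM, median-of-ratios scaling, quantile normalization, TPM recomputed without mitochondrially encoded genes, moderation without trend or with robust variances, a replicate block, leaving out each library, a minimum fold change of 2, an estimated correlation and fry for the lists, and other definitions of detection, cells and genes for the single cells. Alternatives chosen after seeing the data left out genes on chromosomes 16, 20 and 22 and the sex chromosomes, alone and with median-of-ratios scaling, or genes inside the regions covered by alternate contigs.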

Results

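Gene expression was measured in human pluripotent cells by bulk RNA sequencing and by single-cell RNA sequencing. The bulk data comprised 2 libraries of HUES8, an established human embryonic stem cell (ESC) line, and 2 libraries of converted extended pluripotent stem cells (EPSC), pluripotent cells held in a culture state reported to widen their developmental range. The labels did not name the line from which the EPSC were converted. A difference between HUES8 ESC and EPSC may thus reflect the line as well as the culture state. Words such as rose and fell below compare the 2 groups only. A further 25 samples were single EPSC (ffEPSC) converted and kept without feeder cells on Matrigel, a basement-membrane matrix. The bulk values were TPM, transcript abundances relative to the library total, for 19907 genes, which keep no read totals, so the depth of these libraries is unknown. The single cells were deposited as read counts, with 13960701 to 19132581 reads assigned to genes per cell (median 16291400) and 9424 to 11878 genes detected per cell (median 10497).

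Across genes, which are not independent replicates, Spearman's rho was 0.988 between the 2 HUES8 ESC libraries and 0.993 between the 2 EPSC libraries. Between the groups it ranged from 0.908 to 0.921. Transcripts encoded by the mitochondrial genome took 20% ± 0.651 (SD, n = 2) of TPM in HUES8 ESC and 29.8% ± 1.32 (SD, n = 2) in EPSC, and the transcripts of ribosomal protein genes took 5.75% ± 0.112 and 4.02% ± 0.121.

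The first comparison asked how the transcriptome differed between HUES8 ESC and converted EPSC, with attention to the epigenetic and metabolic genes that the study's title names. Of 28 listed genes of naive pluripotency, the state of the pre-implantation embryo, 16 reached the level tested. Of these 13 were higher and 1 lower in EPSC, and the list passed the list test (adjusted p = 0.54 with an estimated correlation). DPPA3, a maternal factor that protects DNA from demethylation, rose from 8.18 ± 2.96 to 257 ± 30.6 TPM, and DNMT3L, a cofactor of the de novo DNA methyltransferases, rose from 0.408 ± 0.577 to 22.5 ± 1.34 TPM (SD, n = 2 per group). The transcription factor ZIC2, typical of the primed, post-implantation state, fell from 275 ± 29.3 to 47.9 ± 7.81 TPM, and DUSP6, a phosphatase induced by ERK signalling, fell from 223 ± 15.4 to 11.1 ± 3.68 TPM. Of 24 genes of DNA replication 15 were higher in EPSC, as were all 13 mitochondrially encoded mRNAs, whereas most ribosomal protein genes and most genes of lipid synthesis, the response to hypoxia and the extracellular matrix were lower on the deposited scale (of 73 ribosomal protein genes 61, and 25 after median-of-ratios scaling). These lists passed the list test with a preset correlation but not with an estimated correlation (adjusted p from 0.54 to 0.58), and quantile normalization ended the call of the mitochondrially encoded mRNAs (adjusted p = 0.20).

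Of 13122 genes tested with limma, 1868 were higher and 5543 lower in EPSC at an adjusted p under 0.05. The median log2 fold change of all genes was -0.26, so that 74.8% of the calls were lower in EPSC. After median-of-ratios scaling, which moved this median to 0.02, 3562 genes were higher and 3529 lower (49.8% lower). With quantile normalization the counts were 3504 and 3305 (48.5% lower), and with mitochondrially encoded genes removed before rescaling they were 2769 and 4140 (59.9% lower). The balance of higher and lower calls therefore depended on the scaling, and list medians are given below relative to the median of all genes, with the counts after median-of-ratios scaling beside them. Changes of at least 4-fold on the log2(TPM + 1) scale were fewer, with 94 genes higher and 402 lower, or 130 and 279 after median-of-ratios scaling. Without EPSC replicate 1 the counts fell to 1129 higher and 3685 lower, and without EPSC replicate 2 to 1160 higher and 4066 lower.

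Among the 8 largest rises were cancer-testis genes, zinc-finger genes and an imprinted gene. The cancer-testis gene MAGEA4 (chromosome X, 151912495 to 151925171 on hg38) rose from 0.0654 ± 0.0925 to 202 ± 3.14 TPM, a log2 fold change of 7.57 with an SE of 0.14 (adjusted p = 4.8e-08). MAGEB2 (chromosome X, 30215563 to 30220089) rose from 0.219 ± 0.133 to 138 ± 14.7 TPM, and the RNA helicase gene DDX43 (chromosome 6, 73394828 to 73417566) from 0.404 ± 0.0645 to 57.6 ± 5.38 TPM. ZNF729 (chromosome 19, 22286441 to 22317176) rose from 0.0652 ± 0.0922 to 40.7 ± 1.15 TPM. PEG3, a paternally expressed imprinted gene on chromosome 19, and the zinc-finger genes ZNF208, ZNF723 and ZNF492 were listed at 0 in both HUES8 ESC libraries. In the EPSC libraries PEG3 stood at 44.3 and 52.3 TPM, ZNF208 at 39.3 and 40.7, ZNF723 at 34.4 and 34.6, and ZNF492 at 31.7 and 32.1. All 8 passed the test, with adjusted p between 4.8e-08 and 5.2e-07.

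The 8 largest falls included those of transcription factor, transporter and signalling genes. The transcription factor gene ZIC1 (chromosome 3, 147393422 to 147510293) fell from 86.6 ± 7.71 to 0.895 ± 0.00717 TPM, a log2 fold change of -5.53 with an SE of 0.14 (adjusted p = 1.8e-07). FEZF1, a forebrain transcription factor gene on chromosome 7, fell from 40.9 ± 6.46 to 0.25 ± 0.0775 TPM, and STMN2, a neuronal microtubule regulator, from 55.6 ± 14.6 to 1.49 ± 1.25 TPM. The palmitoyltransferase gene ZDHHC22 fell from 135 ± 1.36 to 3.87 ± 0.183 TPM, the tyrosine kinase gene LCK from 48.3 ± 2.91 to 1.82 ± 0.956 TPM and the amino acid transporter gene SLC6A15 from 23 ± 2.4 to 0.404 ± 0.0585 TPM. CER1, a secreted NODAL antagonist of the endoderm, fell from 39.7 ± 26.7 to 0.958 ± 0.427 TPM, with a wide spread between the HUES8 ESC libraries. DUSP6 completed the group, and the adjusted p of the 8 lay between 1.3e-07 and 5.4e-05.

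Naive pluripotency genes that reached the level tested were mostly higher. The list holds 28 genes, and those not measured lay under the filter of a mean of 1 TPM. This filter can keep a gene that only 1 group expresses, such as DNMT3L. Of 16 measured, 13 were higher, 1 lower and 2 did not pass, and adjusted over the list alone 14 were higher and 1 lower (14 and 1 after median-of-ratios scaling). The list median was 1.52 above that of all genes, and camera gave an adjusted p of 2.2e-09 (adjusted p = 0.54 with an estimated correlation). Besides DPPA3 (log2 fold change 4.85, adjusted p = 1.5e-06) and ZNF729, the placental-type alkaline phosphatase gene ALPG rose from 2.26 ± 0.467 to 25.1 ± 0.365 TPM. KLF4, a transcription factor of the naive network, rose from 9.47 ± 2.56 to 37.4 ± 2.37 TPM, and TFAP2C, shared by naive cells and trophectoderm, rose from 56.1 ± 7.1 to 112 ± 3.99 TPM.

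Primed genes went mostly the other way without passing the list test. Of 22 measured, 5 were higher, 16 lower and 1 did not pass, also when adjusted over the list alone (5 and 14 after median-of-ratios scaling), and camera gave an adjusted p of 0.11, which became 0.035 after median-of-ratios scaling. With an estimated correlation the list did not pass on either scale (adjusted p = 0.57 on the deposited scale). Besides DUSP6 and ZIC2, ZIC5 fell from 85.4 ± 7.64 to 22.1 ± 1.38 TPM and the cadherin gene CDH2 from 102 ± 11.1 to 37.2 ± 4.33 TPM.

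Core pluripotency genes passed the list test in the upward direction but held members of both directions. Of 23 measured, 12 were higher, 6 lower and 5 did not pass, also when adjusted over the list alone (14 and 4 after median-of-ratios scaling), with a median 0.73 above that of all genes. The camera adjusted p was 0.0067 (adjusted p = 0.57 with an estimated correlation), and it was 0.093 with quantile normalization. With genes on chromosomes 16, 20 and 22 and the sex chromosomes left out, the list median moved from 0.47 to 0.058, against -0.31 for all genes then tested, and the adjusted p was 0.022, or 0.073 with median-of-ratios scaling added. PRDM14, a regulator of the pluripotent state, rose from 156 ± 1.79 to 281 ± 2.15 TPM, FGF4 from 14.4 ± 1.43 to 37.9 ± 6.72 TPM and the NODAL target LEFTY2 from 11.8 ± 5.74 to 73.5 ± 31.8 TPM. The pluripotency factor SOX2 stood at 464 ± 44.2 and 441 ± 24.3 TPM and did not pass (log2 fold change -0.071, adjusted p = 0.56). NANOG fell from 210 ± 10.4 to 119 ± 24.6 TPM (log2 fold change -0.83, adjusted p = 0.001). POU5F1, which encodes OCT4, stood at 59.6 ± 26.1 and 13.7 ± 8.65 TPM (log2 fold change -2.11, adjusted p = 0.0021, and 0.105 with robust variance moderation, the highest of 16 alternatives). It lies on chromosome 6 in a part of hg38 that an alternate contig also covers. Over all such parts 72 of 134 genes well detected in the single cells were listed under 1 TPM in the bulk libraries, and on chromosome 6 34 of 44, so its bulk level is unreliable.

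**Figure D1:**
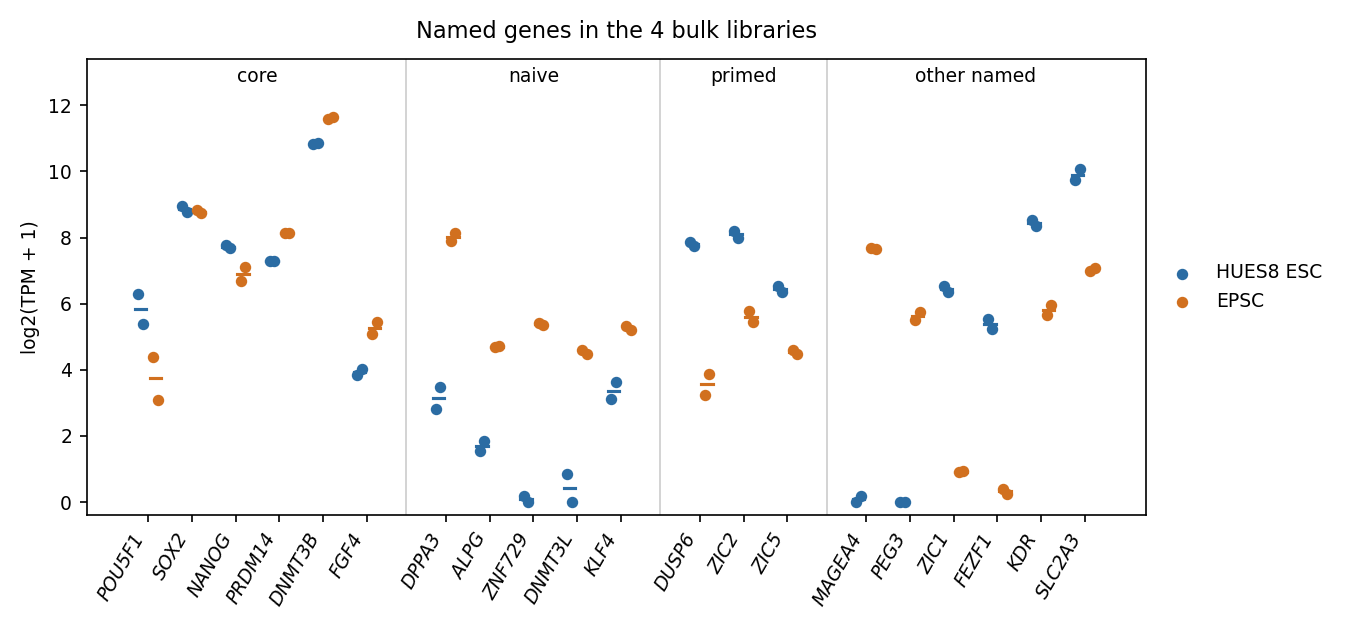
Expression of named genes in the 4 bulk libraries, as log2(TPM + 1), with a point per library and a short bar at the mean of each group (blue, HUES8 ESC; orange, EPSC; n = 2 each). DPPA3, ALPG, ZNF729, DNMT3L and KLF4 lie higher in both EPSC libraries, DUSP6, ZIC2 and ZIC5 lie lower, and the SOX2 points of the groups overlap.

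Markers of other lineages went both ways, and none of these lists passed the list test, although other settings called some of them. Without the filter on low values the cleavage-stage list (adjusted p = 1.5e-06) and the trophectoderm list (adjusted p = 0.034) passed upward, but with an estimated correlation 0 lists passed at that setting. In the trophectoderm and trophoblast list, 4 of 12 measured genes were higher, 3 lower and 5 did not pass, also when adjusted over the list alone (7 and 2 after median-of-ratios scaling), and KRT7 fell from 5.44 ± 0.945 to 0.279 ± 0.101 TPM. Genes of cleavage-stage genome activation were largely below the level tested, with 2 of 5 measured genes higher, 2 lower and 1 not passing, also when adjusted over the list alone (2 and 1 after median-of-ratios scaling). Primitive endoderm genes gave 3 higher, 4 lower and 4 not passing of 11, also when adjusted over the list alone (4 and 4 after median-of-ratios scaling), and the laminin gene LAMA1 fell from 67.3 ± 9.5 to 12.6 ± 0.195 TPM. Amnion genes gave 4 higher, 5 lower and 2 not passing of 11, or 4 and 6 adjusted over the list alone (4 and 4 after median-of-ratios scaling).

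Of 13 mesoderm and primitive streak genes, 3 were higher, 7 lower and 3 did not pass, also when adjusted over the list alone (4 and 6 after median-of-ratios scaling). The receptor gene KDR fell from 347 ± 30.9 to 55.4 ± 8.49 TPM, TBX5 fell from 10.6 ± 3.58 to 0.115 ± 0.0586 TPM and CDX4 rose from 0.7 ± 0.425 to 19.7 ± 0.395 TPM. Definitive endoderm genes gave 2 higher, 4 lower and 1 not passing of 7, or 2 and 5 adjusted over the list alone (2 and 4 after median-of-ratios scaling), and EOMES fell from 6.84 ± 3.81 to 0.893 ± 0.341 TPM. Neural ectoderm genes gave 4 higher, 7 lower and 4 not passing of 15, or 4 and 8 adjusted over the list alone (6 and 6 after median-of-ratios scaling), and SIX3, a forebrain and eye transcription factor gene, fell from 45.7 ± 4.77 to 8.62 ± 1.22 TPM.

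Markers of cell types that a culture could hold beside pluripotent cells were not higher as groups, apart from germ cell genes without the filter on low values (adjusted p = 0.037). With an estimated correlation 0 lists passed, also without this filter or after median-of-ratios scaling. Among fibroblast and stromal markers 0 of 16 were higher, 10 were lower and 6 did not pass, or 0 and 11 adjusted over the list alone (1 and 9 after median-of-ratios scaling). The camera adjusted p of this list was 0.087, and 0.039 after median-of-ratios scaling, and the collagen gene COL1A2 fell from 49.1 ± 0.97 to 14.4 ± 0.536 TPM. All 4 measured endothelial and blood markers were lower, also when adjusted over the list alone (0 higher and 3 lower after median-of-ratios scaling), which is too few for the list test. Epithelial markers gave 1 higher, 11 lower and 5 not passing of 17, also when adjusted over the list alone (3 and 6 after median-of-ratios scaling; camera adjusted p = 0.045 without the filter on low values), and the small GTPase gene RAB25 fell from 81.9 ± 12.9 to 6.94 ± 0.663 TPM. Germ cell genes gave 4 higher, 2 lower and 2 not passing of 8, also when adjusted over the list alone (4 and 2 after median-of-ratios scaling). Of these, PIWIL2, of the pathway that silences transposons in the germ line, fell from 23.1 ± 2.86 to 0.645 ± 0.0501 TPM.

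Genes that set or remove DNA methylation did not move as a list, with 5 of 19 higher, 5 lower and 9 not passing, also when adjusted over the list alone (7 and 3 after median-of-ratios scaling; camera adjusted p = 0.18). The members with the smallest p, DNMT3L, UHRF1 and DNMT3B, were higher. The de novo methyltransferase gene DNMT3B (chromosome 20, 32762385 to 32809359) rose from 1844 ± 10.7 to 3139 ± 71.3 TPM, a log2 fold change of 0.77 with an SE of 0.09 (adjusted p = 0.00014). UHRF1, which directs the maintenance methyltransferase to replicated DNA, rose from 44.1 ± 2.2 to 95.4 ± 2.6 TPM.

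Other chromatin lists were mixed. Polycomb genes gave 9 higher, 12 lower and 10 not passing of 31, or 9 and 13 adjusted over the list alone (11 and 5 after median-of-ratios scaling). Within this list PHC1 fell from 533 ± 87.5 to 187 ± 20.3 TPM. Of 30 histone methyltransferase genes, 8 were higher, 9 lower and 13 did not pass, or 8 and 10 adjusted over the list alone (10 and 1 after median-of-ratios scaling). Histone demethylase genes gave 4 higher, 11 lower and 8 not passing of 23, also when adjusted over the list alone (6 and 6 after median-of-ratios scaling). Genes of histone acetylation and deacetylation gave 9 higher, 9 lower and 14 not passing of 32, also when adjusted over the list alone (13 and 5 after median-of-ratios scaling). The acetyltransferase gene KAT7 fell from 137 ± 0.574 to 40.2 ± 2.78 TPM, and the deacetylase gene SIRT1 rose from 93.1 ± 2.18 to 171 ± 3.5 TPM. None of these 4 lists passed the list test.

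Mitochondrially encoded mRNAs were all higher on the deposited scale. Each of the 13 passed in the upward direction, also when adjusted over the list alone (13 and 0 after median-of-ratios scaling), with a median 0.91 above that of all genes and a camera adjusted p of 1.9e-07 (adjusted p = 0.57 with an estimated correlation). MT-ATP6, a subunit of ATP synthase, rose from 12281 ± 610 to 20556 ± 1348 TPM. These genes are among the most abundant, and quantile normalization, which gives the top ranks of every library equal values, ended the list's call (adjusted p = 0.20).

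The nuclear genes of oxidative phosphorylation did not move as a group on the deposited scale. Of 74 measured, 11 were higher, 16 lower and 47 did not pass, or 10 and 12 adjusted over the list alone, and the camera adjusted p was 0.069. The list median was 0.16 above that of all genes. After median-of-ratios scaling 30 were higher and 1 lower and the adjusted p was 0.0047. With an estimated correlation the list did not pass on either scale (adjusted p = 0.80 with an estimated correlation on the deposited scale). UQCR10 rose from 136 ± 4.6 to 354 ± 33.6 TPM and NDUFAB1 from 197 ± 11.7 to 368 ± 6.61 TPM, on chromosomes 22 and 16.

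Lipid synthesis genes were mostly lower in EPSC. For cholesterol synthesis 1 of 25 genes was higher, 22 were lower and 2 did not pass, also when adjusted over the list alone (2 and 13 after median-of-ratios scaling), with a median relative to all genes of -0.41 and a camera adjusted p of 0.0032 (adjusted p = 0.57 with an estimated correlation). The sterol carrier gene STARD4 fell from 59.7 ± 0.153 to 18.7 ± 0.363 TPM and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, from 105 ± 3.37 to 43.6 ± 4.44 TPM. In fatty acid synthesis 0 of 18 were higher, 14 lower and 4 did not pass, or 0 and 15 adjusted over the list alone (1 and 11 after median-of-ratios scaling), with a relative median of -0.77 and a camera adjusted p of 0.0073 (adjusted p = 0.57 with an estimated correlation). The desaturase gene SCD5 fell from 17.5 ± 1.79 to 0.155 ± 0.0614 TPM and ACLY, which makes cytosolic acetyl-CoA from citrate, from 750 ± 103 to 339 ± 19.9 TPM.

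Hypoxia-response genes were mostly lower. None of 23 was higher, 17 were lower and 6 did not pass, also when adjusted over the list alone (1 and 12 after median-of-ratios scaling), with a relative median of -0.50 and a camera adjusted p of 0.0073 (adjusted p = 0.58 with an estimated correlation). The glucose transporter gene SLC2A3 fell from 962 ± 154 to 130 ± 5.69 TPM. It also belongs to the glycolysis list, of whose 25 genes 3 were higher, 16 lower and 6 did not pass, also when adjusted over the list alone (5 and 9 after median-of-ratios scaling), and which did not pass the list test (adjusted p = 0.22).

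Other metabolic lists did not pass the list test. Tricarboxylic acid cycle genes gave 6 higher, 9 lower and 11 not passing of 26, also when adjusted over the list alone (12 and 5 after median-of-ratios scaling). The mitochondrial isocitrate dehydrogenase gene IDH2 fell from 113 ± 7.54 to 21.1 ± 0.894 TPM, whereas PDHA1, of the pyruvate dehydrogenase complex, rose from 131 ± 0.89 to 314 ± 5.03 TPM. Serine, one-carbon and methionine genes gave 2 higher, 9 lower and 12 not passing of 23, also when adjusted over the list alone (7 and 6 after median-of-ratios scaling). Glutamine and amino acid supply genes gave 6 higher, 5 lower and 8 not passing of 19, also when adjusted over the list alone (10 and 3 after median-of-ratios scaling). Of these 19 genes, 4 lay on chromosomes 16, 20 and 22 or the sex chromosomes. The amino acid transporter gene SLC7A5 rose from 328 ± 0.0078 to 518 ± 6.67 TPM. Fatty acid oxidation genes gave 1 higher, 8 lower and 13 not passing of 22, also when adjusted over the list alone (6 and 8 after median-of-ratios scaling), and CPT1C fell from 35.5 ± 0.664 to 7.89 ± 0.325 TPM. Pentose phosphate and nucleotide synthesis genes gave 8 higher, 9 lower and 7 not passing of 24, also when adjusted over the list alone (10 and 4 after median-of-ratios scaling).

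DNA replication genes passed the list test in the upward direction and ribosomal protein genes in the downward direction. Of 24 genes of the G1/S transition and DNA replication, 15 were higher, 0 lower and 9 did not pass, also when adjusted over the list alone (20 and 0 after median-of-ratios scaling), with a relative median of 0.65 and a camera adjusted p of 8.6e-08 (adjusted p = 0.54 with an estimated correlation). Among the 24 genes, 6 lay on chromosomes 16, 20 and 22 or the sex chromosomes. Many genes on chromosomes 16, 20 and 22 were shifted upward as described below. With genes on chromosomes 16, 20 and 22 and the sex chromosomes left out, the list still passed upward at the preset correlation (camera adjusted p = 5.3e-07). The replication helicase factor CDC45 rose from 50.3 ± 2.01 to 102 ± 4.56 TPM and DTL from 64.5 ± 0.384 to 127 ± 8.56 TPM. Genes of mitosis gave 5 higher, 7 lower and 14 not passing of 26, also when adjusted over the list alone (11 and 2 after median-of-ratios scaling; camera adjusted p = 0.22). Of these 26 genes, 4 lay on chromosomes 16, 20 and 22 or the sex chromosomes. The mitotic kinase gene PLK1 rose from 181 ± 5.2 to 312 ± 7.61 TPM and the checkpoint kinase gene BUB1B fell from 249 ± 37.7 to 109 ± 0.372 TPM. Rises of single genes on the shifted chromosomes were not separated from that shift. Among 73 ribosomal protein genes, 3 were higher, 61 lower and 9 did not pass, also when adjusted over the list alone (4 and 25 after median-of-ratios scaling), with a relative median of -0.23 and a camera adjusted p of 3.2e-05 (adjusted p = 0.57 with an estimated correlation). RPL13A fell from 4261 ± 352 to 1857 ± 72.9 TPM.

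Extracellular matrix and adhesion genes were mostly lower. Of 35 measured, 4 were higher, 25 lower and 6 did not pass, also when adjusted over the list alone (7 and 21 after median-of-ratios scaling), with a relative median of -0.72 and a camera adjusted p of 0.013 (adjusted p = 0.57 with an estimated correlation). The matrix protease gene MMP2 fell from 135 ± 5.37 to 23.4 ± 5.45 TPM and the integrin gene ITGA3 from 16.4 ± 1.77 to 1.65 ± 0.102 TPM.

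Targets of signalling pathways were divided, and none of these lists passed the list test, although that of WNT and beta-catenin did with a filter of 5 TPM (adjusted p = 0.048). With an estimated correlation 0 lists passed at that filter. Of 22 targets of FGF and ERK, 4 were higher, 15 lower and 3 did not pass, or 4 and 16 adjusted over the list alone (5 and 12 after median-of-ratios scaling). In this list DUSP6 fell while the immediate-early genes EGR1 and FOS rose, from 2.05 ± 0.63 to 55.2 ± 1.89 TPM and from 14.7 ± 1.11 to 96.6 ± 0.621 TPM. WNT and beta-catenin targets gave 7 higher, 6 lower and 4 not passing of 17, also when adjusted over the list alone (8 and 3 after median-of-ratios scaling). LIF and STAT3 targets gave 4 higher, 7 lower and 10 not passing of 21, also when adjusted over the list alone (8 and 6 after median-of-ratios scaling), and SOCS3, a feedback inhibitor of the pathway, fell from 41.0 ± 1.44 to 9.56 ± 1.64 TPM.

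Targets of NODAL, activin and TGF-beta gave 5 higher, 7 lower and 9 not passing of 21, also when adjusted over the list alone (6 and 6 after median-of-ratios scaling). Of 13 BMP targets, 5 were higher, 3 lower and 5 did not pass, also when adjusted over the list alone (6 and 3 after median-of-ratios scaling). ID1, which lies at 20q11.21 on the upward-shifted chromosome 20 described below, rose from 116 ± 4.18 to 259 ± 22.5 TPM. Its paralogs ID2 and ID3 fell, from 121 ± 10.4 to 24.5 ± 4.62 TPM and from 249 ± 42.6 to 49.2 ± 7.7 TPM. YAP and TEAD targets gave 3 higher, 15 lower and 2 not passing of 20, also when adjusted over the list alone (4 and 13 after median-of-ratios scaling), and TEAD1 fell from 59.8 ± 2.19 to 18.2 ± 2.57 TPM.

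**Figure D2:**
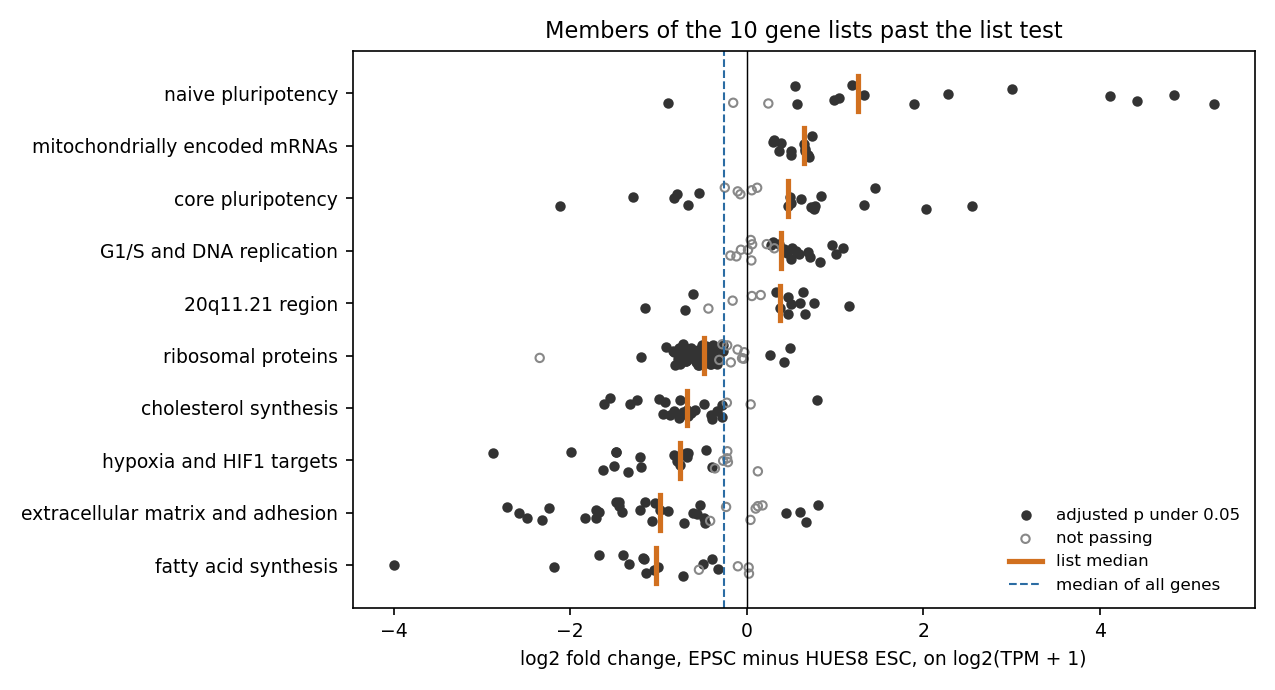
Log2 fold change on log2(TPM + 1) of each member of the 10 lists past the list test, with filled points for genes past an adjusted p of 0.05, open points for others, an orange bar at the list median and a dashed line at the median of all genes (-0.26). Medians of 5 lists lie above that of all genes and those of the other 5 lie below it.

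Genes on chromosomes 16, 20 and 22 stood apart from those on the other 19 autosomes, as seen after the data had been examined. Their median log2 fold changes relative to all genes were 0.46 over 605 genes, 0.41 over 365 genes and 0.39 over 305 genes, while the medians of the other autosomes lay between -0.16 and 0.05. Each EPSC library showed these shifts against each HUES8 ESC library, with medians from 0.42 to 0.50 on chromosome 16, from 0.35 to 0.40 on chromosome 20 and from 0.37 to 0.45 on chromosome 22. The fixed list of genes at 20q11.21, a region often gained in cultured pluripotent cells, lies within the shifted chromosome 20. Of its 17 measured genes 10 were higher, 3 lower and 4 did not pass, also when adjusted over the list alone (11 and 2 after median-of-ratios scaling), with a relative median of 0.64 and a camera adjusted p of 0.0016 (adjusted p = 0.57 with an estimated correlation). ID1, DNMT3B and MAPRE1 led it, and MAPRE1 rose from 322 ± 23 to 510 ± 0.385 TPM. With genes on these chromosomes and on the sex chromosomes left out, 1148 genes were higher and 5235 lower of 11319, and with median-of-ratios scaling added 2487 were higher and 3295 lower.

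**Figure D3:**
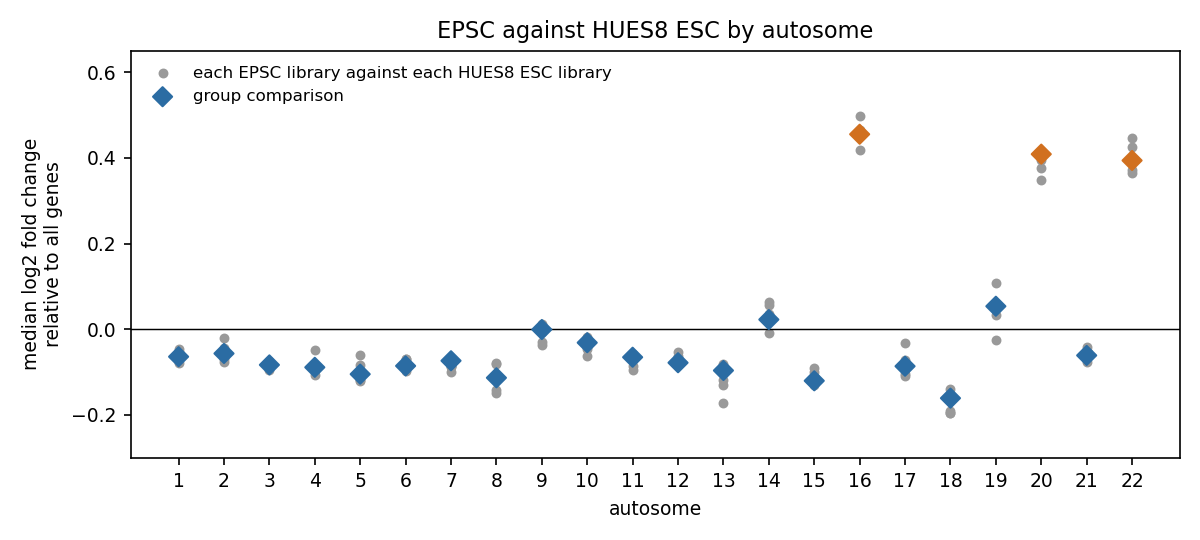
Median log2 fold change of the genes on each autosome relative to all genes, with diamonds for the group comparison (orange for chromosomes 16, 20 and 22, blue for the others) and grey points for each EPSC library against each HUES8 ESC library. The medians of chromosomes 16, 20 and 22 lie at 0.46, 0.41 and 0.39, above all others.

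With camera at the preset correlation 10 of 48 lists passed. With a correlation estimated from the 4 libraries 0 passed, while 2 had an unadjusted p under 0.05. It was also 0 after median-of-ratios scaling or quantile normalization, without the filter on low values and with a filter of 5 TPM. An estimated correlation recovered 0 of 5 simulated lists as well. The test fry, which asks whether a list moves on balance, passed 22. In 18 of the 38 lists that did not pass, the list median and the direction of the test against all other genes differed in sign.

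The single cells addressed whether feeder-free EPSC carried the pluripotency transcripts in every cell. POU5F1, SOX2 and NANOG were all detected in 25 of 25 cells (100%, exact Clopper-Pearson 95% interval 86.3 to 100%). Mean levels were 1044 CPM (reads scaled to a common library total) for POU5F1, 38.7 CPM for SOX2 and 189 CPM for NANOG. L1TD1, an RNA-binding protein of pluripotent cells, and the NODAL co-receptor gene TDGF1 were also found in all 25 cells, at 1160 and 1001 CPM. The labels name no separate cultures, so the cells are 1 sample, no test between cells was made, and intervals cover counting error only.

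All 23 core pluripotency genes were detected in at least 13 of the 25 cells, and 19 of them in all 25. Of 28 naive genes, 10 were detected in at least 13 cells and 4 in none. DNMT3L, ZFP42 and TFAP2C were found in all 25 cells, at means of 274, 121 and 71.5 CPM, and DPPA3 in 20 of 25 (80%, interval 59.3 to 93.2%) at 16.7 CPM. Of 24 primed genes, 21 were detected in at least 13 cells, with CD24, DNMT3B and THY1 in all 25 at 924, 502 and 224 CPM. The cells held transcripts of both lists.

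None of 14 definitive endoderm genes was detected in at least 13 cells, and the most frequent, AFP and EOMES, were found in 10 of 25 (40.0%, interval 21.1 to 61.3%). Of 25 cleavage-stage genes 2 reached 13 cells, NFYA in 24 and DPPA3 in 20, and 17 were found in none. Trophectoderm and trophoblast genes reached 13 cells in 6 of 29 cases, led by the keratin genes KRT8, KRT18 and KRT19, which epithelial cells also express, at 1387, 1073 and 84.9 CPM. For mesoderm and primitive streak 4 of 22 genes did so, with KDR in all 25 cells at 55.6 CPM. Neural ectoderm genes reached that level in 4 of 27 cases, primitive endoderm genes in 7 of 19 and amnion genes in 5 of 18, of which ID1 had a mean of 696 CPM. Fibroblast and stromal markers did so in 9 of 25 cases, epithelial markers in 15 of 17, germ cell genes in 4 of 16 and endothelial and blood markers in 2 of 20.

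The genes that varied most for their level, among 3552 with a mean of at least 50 CPM, were LEFTY2, SERPINB9, MT1G, HIST1H4C, ADM, SPP1, DNMT3L and MT1X. LEFTY2 ranged from 0.443 to 1451 CPM with a coefficient of variation of 1.28. DNMT3L ranged from 1.82 to 1092 CPM, and the protease inhibitor gene SERPINB9 from 25.6 to 1716 CPM. The metallothionein gene MT1G ranged from 66.1 to 1625 CPM, the replication-dependent histone gene HIST1H4C from 203 to 2556 CPM and the secreted phosphoprotein gene SPP1 from 27.2 to 1048 CPM.

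**Figure D4:**
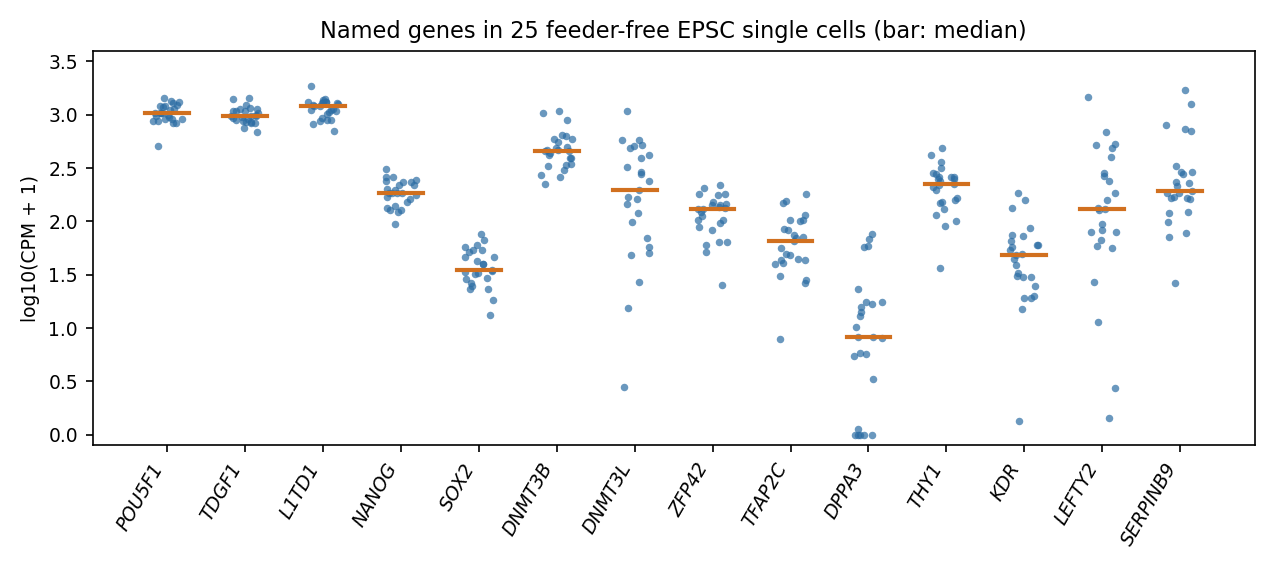
Expression of named genes in the 25 feeder-free EPSC, as log10(CPM + 1), with a point per cell and a bar at the median. POU5F1, SOX2 and NANOG lie above 0 in all 25 cells, whereas DPPA3 was detected in 20 and LEFTY2 and DNMT3L spread widely.

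The second comparison set the single cells beside the bulk groups by rank within each library, since the tables were normalized separately. Over 13122 genes, Spearman's rho of a cell with the mean of the EPSC libraries was 0.674 to 0.747 (median 0.712), and with the mean of the HUES8 ESC libraries 0.637 to 0.711 (median 0.671). All 25 cells were closer to EPSC (100%, exact interval 86.3 to 100%), by 0.025 to 0.053. These correlations run across genes, which are not independent replicates, and the single-cell and bulk assays also differ in library preparation. CPM were not divided by gene length, unlike TPM, and such differences apply to all 25 cells alike.

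The largest bulk rises were mostly scarce in the cells. MAGEA4 was detected in 3 of 25 cells, MAGEB2 in 5 and DDX43 in 3, and PEG3, ZNF208, ZNF729, ZNF723 and ZNF492 in 0 of 25, which allows a share of up to 12% of cells with a read by a limit of 3 cells, or 13.7% by the exact interval. Among the largest bulk falls, ZIC1 and STMN2 were detected in 3 cells, CER1 in 2 and FEZF1 in 10, whereas DUSP6 was detected in 22, ZDHHC22 in 21, LCK in 18 and SLC6A15 in 25. Of 74 genes at least 4-fold higher in bulk EPSC with a mean of at least 10 TPM there, 36 were detected in at least 13 cells (48.6%) and 10 in none. Of 291 genes at least 4-fold lower with at least 10 TPM in HUES8 ESC, 155 reached 13 cells (53.3%) and 11 were found in none. Among 3257 genes without a call at 10 to 100 TPM, 3134 reached 13 cells (96.2%).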

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

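The settings that left out chromosomes or genes covered by alternate contigs were chosen after the results were seen, and the others were fixed beforehand. Of 2319 values of 140 named genes under the alternatives, 2311 kept their direction and their side of the threshold. These genes were named largely for a large change or a small p in the same data, which favours their stability. Over all genes a smaller share of calls was kept, as given below. The count of genes higher in EPSC, 1868 on the deposited scale, was 3562 with median-of-ratios scaling and 3504 with quantile normalization, and the count lower, 5543, was 3529 and 3305. Of the 7411 calls on the deposited scale, 5397 were kept in their direction with median-of-ratios scaling and 5164 with quantile normalization. A scaling by construction moves genes near the median across 0. Leaving out a library gave 1129 to 2020 genes higher and 3685 to 5999 lower, with the lone library of a group assumed to vary like the other group. A minimum fold change of 2 left 475 and 2008 by construction. With genes on chromosomes 16, 20 and 22 and the sex chromosomes left out, 1148 were higher and 5235 lower, of fewer genes tested, and with median-of-ratios scaling added 2487 and 3295.

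The number of lists passed, 10 on the deposited scale, was 16 without a filter on low values, 22 with fry and 0 with an estimated correlation. In the simulation, 0 of 5 lists shifted by 0.5 on the log2 scale were recovered with an estimated correlation. That test can thus miss real shifts, but the simulated genes were independent of one another. For the 10 lists the correlation estimated from the 4 libraries ran from -0.037 (DNA replication) to 0.31 (20q11.21). Most of these estimates exceeded the preset 0.01. The count of 0 therefore does not decide for or against the lists. The cause of the other differences was not tested. The 10 lists kept their direction in all 167 values under other settings of the gene model and their call in 164. The exceptions were the mitochondrially encoded mRNAs with quantile normalization (adjusted p = 0.20) and the core pluripotency list with quantile normalization (0.093) and with median-of-ratios scaling without the named chromosomes (0.073). A further 11 lists passed under at least 1 other setting. A replicate block gave 1937 genes higher, 5670 lower and 17 lists, the cleavage-stage list among them (adjusted p = 0.0028). The deviations of same-numbered libraries correlated at 0.027 with only 2 pairs, so the numbers were not taken to pair the samples.

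The log2 fold change of SOX2, -0.071 and not past the threshold, was 0.23 with median-of-ratios scaling (0.23 also without the named chromosomes), 0.067 with quantile normalization and 0.12 without mitochondrially encoded genes, and it ranged from -0.17 to 0.026 with a library left out, again not past the threshold. That of MT-ATP6 was 0 with quantile normalization, which ties the top ranks, and that of MT-ND4 was 0.059 (adjusted p = 0.295). POU5F1 ranged from -2.75 to -1.47 over 16 alternatives, with adjusted p from 6.89e-33 with the replicate block to 0.105 with robust moderation, where it lost its call. The counts of 25 of 25 cells were equal under all 13 alternatives for the single cells. The unknown depth of the bulk libraries leaves the error of low TPM values unknown, and 25 cells limit a share of 0 to 12% by a limit of 3 cells, or 13.7% by the exact interval.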

Other observations

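The patterns below were noticed in the data, and tests of reads matching both copies of a region, of trends with GC content, length or level, of whole-chromosome gains, of the zinc-finger block in the single cells and of a general rise of its region were chosen after the result was seen. The test of the chromosomes in the single cells is given as its prediction was written beforehand. It had first been applied with a lower bound from the medians after trends were removed, which argued against a shared shift for chromosomes 16 and 20, and then, after its values were seen, with a stricter upper bound, which left chromosome 22 open.

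Replication-dependent histone genes, a group chosen after the data were seen and not put to the list test, were mostly higher in EPSC on the deposited scale. Of 48 measured, 32 were higher, 0 lower and the rest did not pass, with a median log2 fold change of 1.07. They were not counted after median-of-ratios scaling. Their summed level was 473 ± 102 TPM in HUES8 ESC and 1311 ± 382 TPM in EPSC (SD, n = 2). Imprinted genes gave 4 higher, 14 lower and 3 not passing of 21, also when adjusted over the list alone (5 and 8 after median-of-ratios scaling). While PEG3 rose, MEST fell from 257 ± 46.5 to 65.5 ± 0.72 TPM and ZDBF2 from 11.5 ± 1.2 to 1.34 ± 0.0874 TPM, and in the single cells MEST was detected in all 25 at a mean of 490 CPM. Interferon and antigen presentation genes gave 5 higher, 5 lower and 4 not passing of 14, also when adjusted over the list alone (5 and 5 after median-of-ratios scaling). IFITM3, a membrane protein that restricts viral entry, rose from 455 ± 26 to 1103 ± 48.9 TPM and BST2, which tethers budding virus, from 108 ± 13.1 to 400.1 ± 43 TPM.

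Targets of p53 gave 1 higher, 13 lower and 9 not passing of 23, also when adjusted over the list alone (3 and 11 after median-of-ratios scaling), and TP53INP1 fell from 11.3 ± 0.517 to 1.98 ± 0.216 TPM. Apoptosis regulators gave 3 higher, 9 lower and 10 not passing of 22, or 4 and 9 adjusted over the list alone (7 and 6 after median-of-ratios scaling). The pro-apoptotic BMF fell from 42.5 ± 9.46 to 5.14 ± 1.09 TPM. Genes of the unfolded protein response and ATF4 gave 6 higher, 5 lower and 13 not passing of 24, or 5 and 5 adjusted over the list alone (11 and 2 after median-of-ratios scaling). Stress and dissociation genes gave 5 higher, 4 lower and 9 not passing of 18, or 7 and 6 adjusted over the list alone (10 and 2 after median-of-ratios scaling). Histamine and muscarinic receptor genes with PARP1 and PARP2 gave 1 higher, 2 lower and 3 not passing of 6, also when adjusted over the list alone (2 and 2 after median-of-ratios scaling), with PARP1 rising from 525 ± 23.1 to 790.1 ± 16.5 TPM and HRH2 falling from 17.1 ± 1.84 to 5.48 ± 1.2 TPM. Housekeeping genes gave 1 higher, 6 lower and 8 not passing of 15, also when adjusted over the list alone (5 and 3 after median-of-ratios scaling). None of these lists, nor the imprinted and interferon lists, passed the list test, although p53 targets passed downward without the filter on low values (adjusted p = 0.019). With an estimated correlation 0 lists passed at that setting. Some other settings called stress and dissociation genes and genes of the unfolded protein response upward.

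Genes inside regions of hg38 that alternate contigs also cover were near 0 in the bulk libraries although the single cells expressed them. Of 134 such genes with a mean of at least 20 CPM in the cells, 72 (53.73%) were under 1 TPM in bulk, against 0 of 456 within 500000 bases outside, which argues against a difference between the cells (0%), and against 3 of 5760 other genes (BDH1, HIST1H1A and TTN). TUBB had 2749 CPM and 0.203 and 0.337 TPM in HUES8 ESC and EPSC, and RPS18 had 1824 CPM and 0.0531 and 0.042 TPM. With a trend on gene length removed, the median log2 gap of the inside genes to the cells was still -4.20, so length does not account for it. A candidate explanation is that bulk reads matching both copies were not counted, and POU5F1, at 1044 CPM in the cells, lies in such a region.

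Genes on chromosomes 16, 20 and 22 were shifted upward in EPSC, and medians after trends with GC content, length and level were removed stayed at 0.61, 0.49 and 0.57, against at most 0.20 on the other autosomes, which argues against those trends. Over blocks of 25 genes, 95.83% on chromosome 16 exceeded the 95th percentile of other autosomes, which would be in line with a gain of the whole chromosome, while 71.43% on chromosome 20 and 66.67% on chromosome 22 leave that open. On chromosome 22 the median was 0.73 up to 36028824 and 0.14 from 36226209, at a boundary chosen after the values were seen. Blocks before it had medians from 0.38 to 1.45. Beyond it the blocks between 39120167 and 42858106 had 0.32 and 0.46, also over that percentile, and the others -0.14 to 0.14. The shift was thus neither even nor bounded there. A gain of part of the chromosome may be weighed, although no DNA was analysed here and regulation without a change in copy number remains open. In the single cells against HUES8 ESC the medians were 0.25, 0.22 and 0.62, against -0.32 to 0.48 (SD 0.21) on the other autosomes. Chromosome 22 ranked 1 of 22 autosomes, where the prediction of a shift shared by the cells asked for the 3 highest, although chromosomes 11 and 14, not shifted in bulk, reached 0.48 and 0.35, while chromosomes 16 and 20 ranked 4 and 5, above the lower bound, so that for them sharing cannot be told apart from differences between the assays.

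A block of 9 neighbouring zinc-finger genes on chromosome 19 (21932958 to 23003176, from ZNF208 to ZNF728) was at or near 0 in HUES8 ESC and at 5.92 to 40.7 TPM in EPSC, and 7 of the 9 were listed at 0 in both HUES8 ESC libraries. Reads shared between paralogs are argued against by the median of 74.03% of 31-base words that no other annotated gene holds. A general rise of the region's zinc-finger genes is argued against by the other 27, of which 3 were higher and 8 lower, with a median of 0.074 relative to all genes. The block was not shared by the single cells, where 0 of the 9 genes reached 13 of 25 cells (8 were found in none), against 5258 of 5835 genes of like TPM (90.1%). Silencing of the block in HUES8 ESC and in the line of the single cells, or a difference between the lines, may be considered as hypotheses, which were not tested because the labels do not name the lines of the EPSC.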
